A study of Mus musculus with 4 samples.

How the data were processed

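Gene expression was measured by RNA sequencing of whole aortic graft tissue from mice, with 2 ISO and 2 ALLO libraries, all from 4 weeks after transplantation. Per the labels' protocols, total RNA was extracted with Trizol, treated with DNase, depleted of ribosomal RNA and amplified by PCR. The authors deposited raw read counts per gene, one column per library, in the column layout that featureCounts writes. Per the submitters' processing notes the tools were Subread 1.6.4 with featureCounts, DESeq2 1.30.0 and R 4.0.3, with the mouse build mm10. The aligner, the annotation release, the strand setting and the treatment of reads that map to several places are not given in the sources used here. Reads of near-identical copies and of overlapping genes may therefore have been split or lost, and genes of such families are reported as uncertain.

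The count table held 54752 Ensembl gene IDs. GENCODE M21 gave names for 53861 of them with their version and for 54723 without it, and 29 had no match. Chromosome, start and end were the same as in that annotation for 54037 genes. Coordinates are from the deposited table, on mm10. Of genes with 1 to 20 counts, 68.0%, 68.6%, 74.6% and 68.1% had an even count in ISO replicate 1, ISO replicate 2, ALLO replicate 1 and ALLO replicate 2, and about as many even as odd counts were found above 100, which is the pattern of pairs whose 2 mates were both counted. A floor of 6 counts per library, or 3 read pairs, was therefore used for genes at 0 in a group, and counting intervals were taken on counts divided by 2.

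Group membership and replicate numbers came from the sample labels. Nothing in the labels says that the libraries came from separate animals, or gives strain or sex. Replicates were compared before use. Chi-square over degrees of freedom was 45.7 in ISO and 154 in ALLO, so no pair agreed within sampling noise, and the Pearson correlation of log2 CPM was 0.961 and 0.950.

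The design, gene lists, naming rule and most alternatives were fixed before the data were examined. Genes were filtered with filterByExpr (minimum count 10), which left 16498 genes (30.1% of the IDs), scaled by TMM (factors 0.926, 0.946, 1.04 and 1.09) and tested with edgeR 4.0.16 (glmQLFit and glmQLFTest, group as the only term), with Benjamini-Hochberg adjusted p under 0.05 as the threshold. The common biological coefficient of variation was 0.324. Standard errors belong to the log2 change. The 34 gene lists, of 503 genes, covered cell types, matrix, antigen presentation, interferon response, inflammation, metabolism and cell division, and came from textbook knowledge. They were tested with camera of limma 3.58.1 (preset correlation 0.01, log2 CPM with a prior count of 2), two-sided and adjusted over all 34. An estimated correlation, which rests on 2 residual degrees of freedom, and fry were alternatives. fry asks whether the members of a list move on balance one way and does not compare them with other genes. With an estimated correlation no list was called, and with fry 14 lists were.

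Named genes were the 10 with the largest log2 change in each direction among those that passed, had a mean of at least 50 counts and lay on the same side in every library, leaving out unnamed models, pseudogenes and immunoglobulin and T cell receptor segments. From each list up to 4 members with the smallest adjusted p in the main direction and up to 2 in the other were added, for 182 genes in all. A selection of them is printed, and a few are not reported here. Of these 182, 134 shared no exonic base with another gene and 1, Tagln, shared more than 50% of its exonic bases. Confidence intervals of shares are 95% Wilson intervals.

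The procedure was tested on simulated counts for 15999 genes with the libraries' own means and sizes. Of 50 genes changed at each size, 2% were recovered at 2-fold, 48% at 4-fold, 86% at 8-fold and 84% at 16-fold. Of 15799 unchanged genes 13 were called, 10.6% of all 123 calls. With 5469 calls in the data, the adjusted threshold was stricter in the simulation, so the shares recovered are not the power of this comparison. Both changed lists and 0 of 34 unchanged lists were called. Simulated genes were drawn independently, so this does not vouch for calls on lists whose members move together. In the data the estimated correlation within lists ranged from 3.53e-05 (bone and cartilage) to 0.964 (neutrophil).

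Alternatives were other scalings (DESeq2 size factors, upper quartile, library size only), no filter or a mean count of 10 or more, the Wald test of DESeq2 1.42.0, limma-voom, limma-trend, glmTreat against 1.5-fold, a replicate block, each library left out in turn, counts thinned to the smallest library, and removal of mitochondrial, ribosomal RNA, immunoglobulin and T cell receptor genes. Halved counts and removal of genes on the X and Y chromosomes were added after the data had been seen. Calculations used R 4.3.3, Python 3.11.15, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.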

Results

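RNA from mouse abdominal aortic grafts was sequenced 4 weeks after transplantation, from which ribosomal RNA had been removed. The grafts formed a group called ALLO, allografts per the series title, and a group called ISO, a name that the labels do not spell out, with 2 libraries in each (n = 2 per group throughout). The libraries held 18488823 counts (ISO replicate 1), 17532344 (ISO replicate 2), 18978538 (ALLO replicate 1) and 20194854 (ALLO replicate 2), with 20686, 19987, 21593 and 22171 genes detected. ISO replicate 1 had 10647 counts of the X inactivation transcript Xist and 0 of the Y-linked gene Ddx3y, while the other libraries had at most 8 of Xist and at least 2105 of Ddx3y. The labels do not say whether the libraries of a group came from separate animals, so the p-values measure only the spread between these samples, which may in part be technical. It is not that of repeat libraries of one RNA, since these counts mark tissue of different sex in ISO, and in ALLO replicates 1 and 2 the immunoglobulin gene Ighv1-81 took 7.10% and 0.981% of heavy chain V counts and Ighv2-9-1 1.08% and 15.5%. Pieces of a single ALLO graft stay possible. Intervals and lower bounds of folds cover counting error only, not the spread between libraries. They may be too narrow even for counting error, since reads amplified by PCR carried no molecular identifiers.

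The comparison asked how allograft aorta in chronic rejection differed from ISO grafts. Contractile genes of smooth muscle were lower in ALLO grafts, in 17 of 18 cases. Higher were genes of T cells (20 of 20), cytotoxic and NK cells (17 of 18), macrophages (17 of 20), MHC class I and II presentation (15 of 15 and 10 of 11), the interferon-gamma and type I interferon responses (16 of 21 and 14 of 17) and cell division (19 of 20). For all of these lists the camera call was lost at adjusted p = 0.555 to 0.556 with an estimated correlation. Itga8, an integrin subunit through which smooth muscle binds matrix (ENSMUSG00000026768.10, chromosome 2, 12106632 to 12301922, mm10), averaged 39.8-fold lower in ALLO, a log2 change of -5.32 ± 0.41 (SE). Cxcl9, a chemokine that draws activated T cells (ENSMUSG00000029417.9, chromosome 5, 92321347 to 92328079), was 98.4-fold higher, at 483 ± 16.4 CPM (normalized for library size and composition) in ALLO against 4.91 ± 0.488 in ISO (mean ± SD, n = 2). Trac, the constant region of the T cell receptor alpha chain (ENSMUSG00000076928.5, chromosome 14, 54220521 to 54224206), was 44.0-fold higher. H2-Aa, an MHC class II chain (ENSMUSG00000036594.14, chromosome 17, 34282744 to 34287827), was 37.9-fold higher.

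Of 16498 genes tested with edgeR's quasi-likelihood test, 5469 passed a Benjamini-Hochberg adjusted p of 0.05, with 3032 higher and 2437 lower in ALLO (55.4% higher). Scaling by library size alone, which moved the median of all genes by 0.19 on the log2 scale, gave 3546 higher and 1867 lower (65.5% higher). Changes are given relative to the composition scaling (TMM). Leaving out ISO replicate 2 left 3603 genes, of which 3417 were among the 5469, and leaving out ISO replicate 1 left 4173, of which 3778 were. Fitted folds moved by over 1.5 times for 426 (without ALLO replicate 1) to 718 (without ISO replicate 2) of the 5469, apart from genes then at 0 counts in a group. Medians and folds given without 1 library come from such fits, in medians with genes at 0 in a group at their bound.

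Genes were ranked by fitted log2 change, which placed several that were absent from one group at the top. All 10 on the higher side had 0 counts in both ISO libraries, so only lower bounds of their folds are given. These bounds, 23.1- to 66.9-fold, lie below the 111-fold of Itgax, which had counts in both ISO libraries. The 10 genes are therefore not shown to have the largest changes. Glycam1, a sialomucin of high endothelial venules that binds L-selectin (ENSMUSG00000022491.5, chromosome 15, 103562759 to 103565081), had 575 and 400 counts in the ALLO libraries and 0 in both ISO libraries, at least 66.9-fold higher. The chemokine gene Ccl22 was at least 50.7-fold higher on the same floor of 6 counts per library. At least 37.6-fold for H2-M2, 33.9-fold for Gpr141b, 25.5-fold for Slc9a7 and 25.1-fold for Samd3 were the next bounds. Fbn2, a fibrillin of developing microfibrils, the neural gene Brinp3, the homeobox gene Hoxc10 and the granzyme gene Gzmk were at least 24.4-, 24.3-, 23.4- and 23.1-fold higher. These 10 genes had edgeR adjusted p values of 0.00345 to 0.00696.

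On the lower side, Mylk4, a myosin light chain kinase family member (ENSMUSG00000044951.15, chromosome 13, 32700834 to 32783954), fell from 481 ± 45.9 to 0.974 ± 0.222 CPM (SD), 494-fold lower (edgeR adjusted p = 0.00214). Sost, which encodes the WNT antagonist sclerostin (ENSMUSG00000001494.6, chromosome 11, 101962458 to 101967015), was 406-fold lower (log2 change -8.67 ± 0.73, edgeR adjusted p = 0.00345), or 812-fold without ALLO replicate 1 and 267-fold without ALLO replicate 2. The R-spondin receptor gene Lgr6 was 254-fold lower, and Vstm2b had 4 counts in ALLO and 1044 in ISO, a ratio of 322 (95% counting interval 88.6 to 2663). Wif1, another secreted WNT inhibitor, had 0 counts in both ALLO libraries and was at least 92.4-fold lower. Sh3rf2 was at least 141-fold lower, Tceal6 at least 60.1-fold and the potassium channel gene Kcnj11 at least 22.8-fold lower. Klhl41, a gene of striated muscle, had 3 counts in ALLO and 504 in ISO, a ratio of 207 (95% counting interval 42.5 to 1289).

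**Figure D1:**
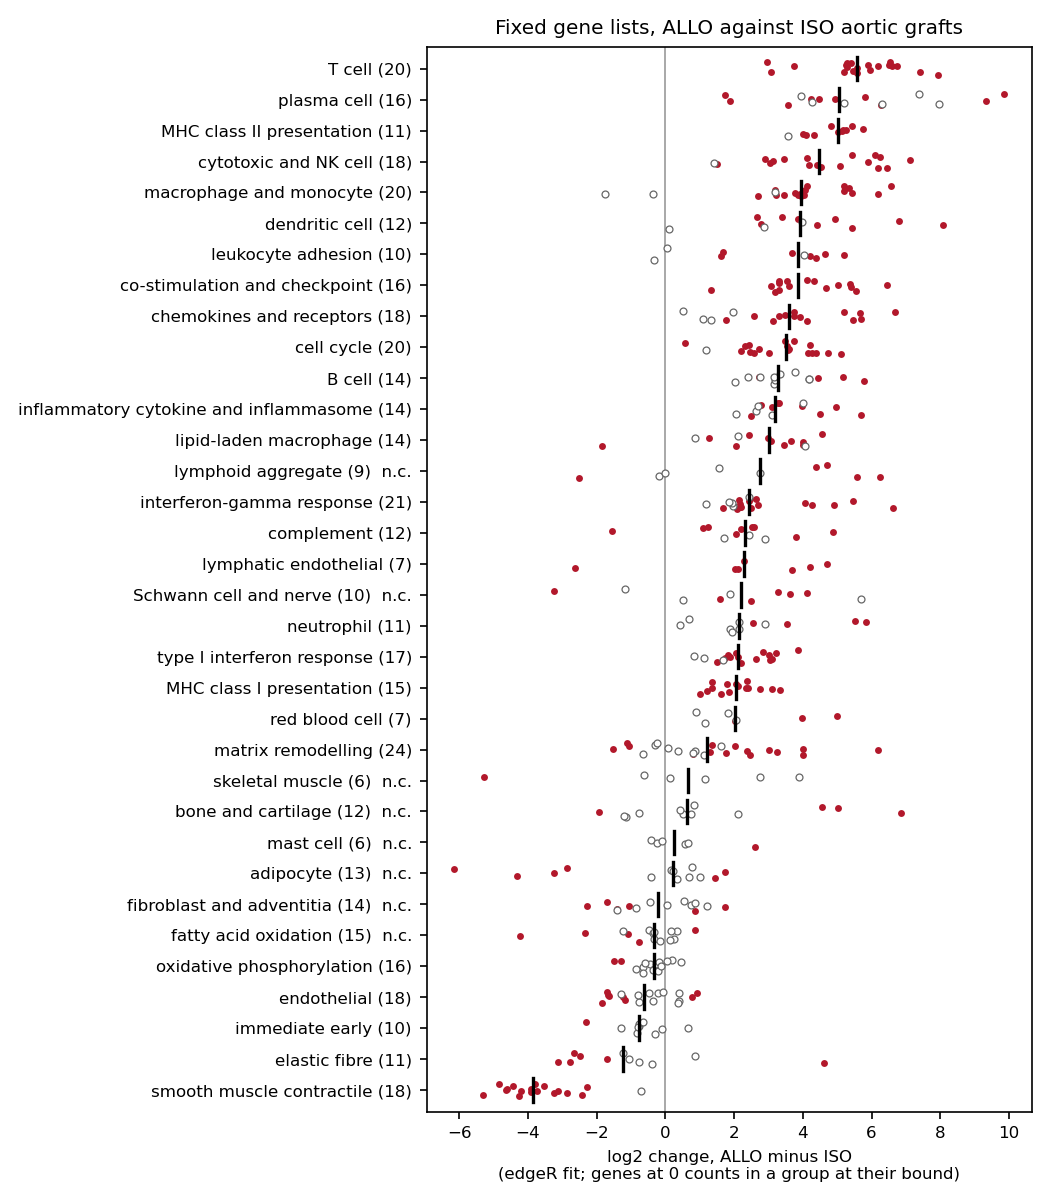
Log2 change, ALLO minus ISO, of each tested member of the 34 gene lists (points, with the number of members in brackets, filled where the edgeR adjusted p passed 0.05, heights within a line being arbitrary) and each list's median (vertical bars), with genes at 0 counts in a group at their lower bound and lists that camera did not call marked n.c. With genes at these bounds, the smooth muscle list has the lowest median, -3.85, and the T cell list the highest, 5.58.

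Of the 18 smooth muscle contractile genes, 17 fell, none rose and 1 did not pass (18 fell when adjusted over the list alone). Their median log2 change was -3.85 (camera adjusted p = 7.62e-11, adjusted p = 0.555 with an estimated correlation). Synpo2, an actin-binding protein of the Z-disc and dense bodies, was 25.0-fold lower and Myocd, the transcriptional coactivator of the contractile programme, 28.8-fold lower. Acta2 and Myh11, which encode smooth muscle actin and myosin and were chosen after their values were seen, changed by -3.74 ± 0.63 and -4.43 ± 0.47 on the log2 scale (edgeR adjusted p = 0.0129 and 0.00477, Acta2 by -4.49 without ALLO replicate 2). Tagln gave -3.79 ± 0.28, but 67.9% of its exonic bases overlap a gene on the opposite strand and the strand setting of the counting is not given, so that value is uncertain. Des, the intermediate filament gene, had a change of -0.72 (edgeR adjusted p = 0.0935), but passed as lower without ALLO replicate 2 (-1.07, edgeR adjusted p = 0.0255). The list's median was -4.54 without ALLO replicate 2. The smooth muscle list differed little between the ISO libraries, by a median of -0.03 (log2, replicate 1 minus replicate 2).

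Elastic fibre genes had a median of -1.25, with 5 of 11 lower and 1 higher (6 lower and 2 higher when adjusted over the list alone, camera adjusted p = 0.0190, adjusted p = 0.566 with an estimated correlation). Without ALLO replicate 2, 8 were lower and the median was -1.86. Ltbp4 and Ltbp1, which tether latent TGF-beta to microfibrils, fell 6.91- and 8.81-fold, and the microfibril gene Mfap4 fell 5.63-fold, while Fbn2 was the member that rose. Eln, which encodes elastin and was chosen after its values were seen, changed by -2.65 ± 0.72 (edgeR adjusted p = 0.0433), and by -3.77 without ALLO replicate 2. Its call was lost without ALLO replicate 1 (3.99-fold, edgeR adjusted p = 0.0570). In the matrix remodelling list 12 of 24 genes rose and 3 fell (14 and 3 when adjusted over the list alone), with a median of 1.21 (camera adjusted p = 0.0182, adjusted p = 0.556 with an estimated correlation, and 0.0820 by camera without ALLO replicate 2), and 1 fell without ISO replicate 2. Col12a1, a fibril-associated collagen, was 8.10-fold higher, the membrane-bound collagenase gene Mmp14 5.46-fold and the macrophage elastase gene Mmp12 73.2-fold higher (230-fold without ISO replicate 1, 42.7-fold without ISO replicate 2). The matricellular gene Postn fell 2.87-fold.

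Bone and cartilage genes gave 3 of 12 higher and 1 lower (the same numbers when adjusted over the list alone), a median of 0.63, and no call (camera adjusted p = 0.463). Runx2, a transcription factor of osteoblast formation, rose 23.9-fold (39.2-fold without ISO replicate 1) and the hypertrophic cartilage collagen gene Col10a1 32.6-fold (21.0-fold without ISO replicate 1, 67.4-fold without ISO replicate 2). Which cells carried the Runx2 transcripts was not tested. The cartilage collagen gene Col2a1 had 2 counts in ISO and 324 in ALLO, a ratio of 131 (95% counting interval 23.3 to 5224). Bmp2, a bone morphogenetic protein gene, fell 3.80-fold, a call lost without ALLO replicate 1 (edgeR adjusted p = 0.0592), and without ALLO replicate 2 3 of 13 fell.

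**Figure D2:**
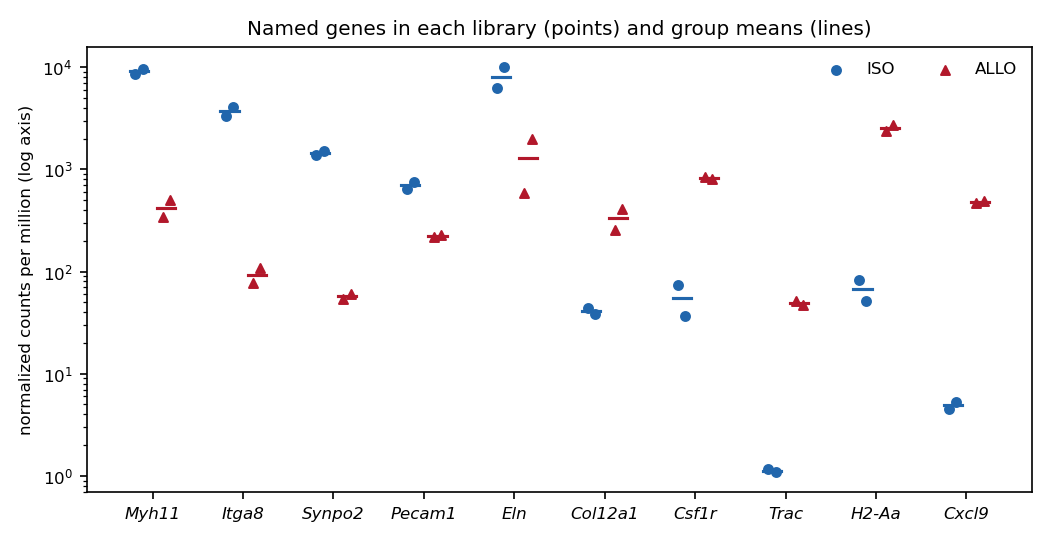
Normalized CPM, on a log axis, of 10 genes in each of the 4 libraries (points) with group means (lines). Itga8, Synpo2 and Myh11 lie lower in both ALLO libraries than in both ISO libraries, and Cxcl9, H2-Aa and Trac lie higher.

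Endothelial genes gave 6 of 18 lower and 2 higher (the same numbers when adjusted over the list alone), with a median of -0.63 (camera adjusted p = 0.0292, adjusted p = 0.556 with an estimated correlation). Erg, a transcription factor of endothelial identity, fell 3.63-fold and the adhesion gene Pecam1 3.14-fold, whereas Plvap, a component of fenestral diaphragms, rose by 0.92 ± 0.24 (log2, edgeR adjusted p = 0.0372), a call lost whenever a library was left out. No member was higher when any 1 library was left out, and 10 were lower without ALLO replicate 2. The list's call was lost without ISO replicate 1 (camera adjusted p = 0.0909) and without ALLO replicate 1 (0.144). Of 7 lymphatic endothelial genes, 6 rose and 1 fell (the same when adjusted over the list alone), with a median of 2.29 (camera adjusted p = 0.0170, adjusted p = 0.556 with an estimated correlation, and 0.0856 by camera without ALLO replicate 1). Prox1, the transcription factor of lymphatic fate, rose 26.2-fold (48.4-fold without ISO replicate 1, 17.1-fold without ALLO replicate 1), the hyaluronan receptor gene Lyve1 4.07-fold and Flt4, a VEGF receptor gene, 4.89-fold, and the semaphorin gene Sema3d fell 6.19-fold (16.7-fold without ALLO replicate 1, 3.77-fold without ALLO replicate 2). The Sema3d call was lost with a mean count of 10 or more (edgeR adjusted p = 0.0517) and against 1.5-fold (0.0627).

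Fibroblast and adventitia genes gave no call (camera adjusted p = 0.463), with a median of -0.21, 4 of 14 lower and 2 higher (5 and 2 when adjusted over the list alone). Pi16, a marker of adventitial fibroblasts, fell 4.82-fold, and the progenitor surface gene Ly6a rose 3.34-fold, a call lost without ISO replicate 2 (edgeR adjusted p = 0.0525). The list's median was -0.10 without ISO replicate 1, -0.34 without ISO replicate 2, -0.68 without ALLO replicate 1 and 0.18 without ALLO replicate 2.

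T cell genes had a median of 5.58, and all 20 rose (20 when adjusted over the list alone, camera adjusted p = 4.35e-09, adjusted p = 0.555 with an estimated correlation). Lck, the proximal kinase of the T cell receptor, was 48.2-fold higher and its partner Zap70 42.9-fold. The co-stimulator gene Icos had 5 counts in ISO and 1587 in ALLO, a ratio of 258 (95% counting interval 73.2 to 1044). Of 18 cytotoxic and NK cell genes, 17 rose and 1 did not pass (18 when adjusted over the list alone, camera adjusted p = 8.10e-09, adjusted p = 0.555 with an estimated correlation). Their median was 6.0, or 4.47 with the genes at 0 counts in ISO set at their bound. Klrk1, the NKG2D receptor gene, was 69.9-fold higher, the granule gene Nkg7 changed by 5.08 ± 0.30 (log2) and the chemokine gene Ccl5 was 73.8-fold higher (128-fold without ISO replicate 1). Fasl, the death ligand gene, had 3 counts in ISO and 551 in ALLO, a ratio of 149 (95% counting interval 30.7 to 929). T cell genes were also higher in ISO replicate 1 than in ISO replicate 2, in 20 of 20 members, by a median of 1.04 on the log2 scale, and without ISO replicate 1 the median of the T cell list was 6.49.

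Of 16 genes for co-stimulation and checkpoints, 16 rose (16 when adjusted over the list alone, camera adjusted p = 4.35e-08, adjusted p = 0.555 with an estimated correlation), with a median of 4.22, or 3.86 at the bounds. They included Tnfrsf4, the OX40 gene (32.9-fold), the ligand gene Cd86 (25.8-fold, 40.9-fold without ISO replicate 1) and the inhibitory receptor gene Lag3 (12.1-fold). The lymphoid aggregate list was not called (camera adjusted p = 0.115, and 0.0219 without ISO replicate 1), with a median of 2.75. In it, 4 of 9 genes rose and 1 fell (5 and 1 when adjusted over the list alone). Without ALLO replicate 1, 2 rose, and without ISO replicate 2 the median was 1.79. The lymphotoxin gene Ltb rose 20.9-fold (55.9-fold without ISO replicate 1, 12.6-fold without ISO replicate 2) and the surface glycoprotein gene Cd200 fell 5.75-fold.

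B cell genes had a median of 3.27, and 4 of 14 rose (1 when adjusted over the list alone, camera adjusted p = 6.31e-04, adjusted p = 0.556 with an estimated correlation). The number that rose hung on single libraries, being 14 without ISO replicate 1, 9 without ISO replicate 2, 1 without ALLO replicate 1 and 3 without ALLO replicate 2. The median was 5.62 without ISO replicate 1 and 2.27 without ISO replicate 2. The complement receptor gene Cr2 had 6 counts in ISO and 412 in ALLO, a ratio of 55.7 (95% counting interval 18.8 to 272, edgeR adjusted p = 0.0106, and 0.0586 with limma-voom). Of 16 plasma cell genes, 10 rose (15 when adjusted over the list alone), with a median of 5.07 (camera adjusted p = 1.44e-05, adjusted p = 0.555 with an estimated correlation). Only 1 of the 16 passed without ALLO replicate 1, against 15 without ISO replicate 1. The median was 7.85 without ISO replicate 1, 4.19 without ISO replicate 2, 4.23 without ALLO replicate 1 and 5.82 without ALLO replicate 2. Sdc1, the plasma cell syndecan that other cells also express, was 3.68-fold higher. Prdm1, the regulator of plasma cell differentiation, was 22.2-fold higher (124-fold without ISO replicate 1, 11.9-fold without ISO replicate 2), a call lost without ALLO replicate 1 (edgeR adjusted p = 0.0704). Immunoglobulin genes took 11.2% and 3.08% of the counts of the ALLO libraries, 0.0699% of ISO replicate 1 and 0.0014% of ISO replicate 2. The widest of these 95% Wilson intervals spanned 0.0401 percentage points. Within ISO, replicate 1 had the higher B cell and plasma cell genes, by medians of 2.37 and 2.61.

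**Figure D3:**
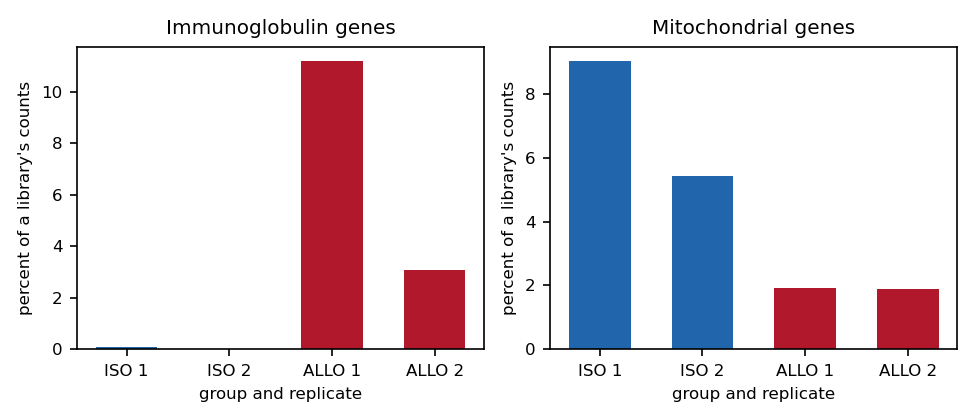
Percent of each library's counts in immunoglobulin genes (left) and in genes of the mitochondrial genome (right), one bar per library, blue for ISO and red for ALLO. Immunoglobulin genes took 11.2% and 3.08% in ALLO, and mitochondrial genes 9.02% and 5.42% in ISO.

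Macrophage and monocyte genes rose in 17 of 20 cases, with none lower (18 when adjusted over the list alone), and had a median of 3.94 (camera adjusted p = 3.55e-07, adjusted p = 0.556 with an estimated correlation). The fractalkine receptor gene Cx3cr1 rose 43.4-fold, the Fc receptor gene Fcgr1 36.6-fold, Csf1r, the receptor of the macrophage growth factor, 15.1-fold, and the monocyte gene Ly6c2 94.7-fold (225-fold without ISO replicate 1, 58.7-fold without ISO replicate 2). Cd163, a gene of resident macrophages, had a change of -1.76 (edgeR adjusted p = 0.116), but passed as lower without ALLO replicate 1 (-3.19, edgeR adjusted p = 0.0140), without the filter on low counts (0.0468), with DESeq2 (0.0350) and with limma-voom (0.0423). All 20 were higher in ISO replicate 1 than in ISO replicate 2, by a median of 1.58, and the list's median was 5.45 without ISO replicate 1 and 3.31 without ISO replicate 2. In the lipid-laden macrophage list 10 of 14 rose and 1 fell (11 and 1 when adjusted over the list alone), with a median of 3.03 (camera adjusted p = 6.26e-05, adjusted p = 0.555 with an estimated correlation). Trem2, a lipid-sensing receptor gene, rose 23.5-fold (58.1-fold without ISO replicate 1, 14.4-fold without ISO replicate 2) and the galectin gene Lgals3 16.1-fold, whereas the tetraspanin gene Cd9 fell 3.62-fold.

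Dendritic cell genes had a median of 3.91, and 9 of 12 rose (10 when adjusted over the list alone, camera adjusted p = 3.06e-05, adjusted p = 0.555 with an estimated correlation). The median was 3.20 without ISO replicate 2. The integrin gene Itgax was 111-fold higher and Clec9a, a receptor of cross-presenting cells, 10.4-fold. The chemokine receptor gene Xcr1 had 2 counts in ISO and 761 in ALLO, a ratio of 309 (95% counting interval 55.2 to 12244). Neutrophil genes had a median of 2.15, and 4 of 11 rose (5 when adjusted over the list alone, camera adjusted p = 0.00365, adjusted p = 0.566 with an estimated correlation). Without ISO replicate 1, 10 of 12 tested rose, without ISO replicate 2 2 of 12 and without ALLO replicate 1 1 of 11. The median was 3.45 without ISO replicate 1, 1.55 without ISO replicate 2 and 2.77 without ALLO replicate 2. Csf3r, the receptor of the granulocyte growth factor, rose 11.6-fold (25.1-fold without ISO replicate 1, 7.37-fold without ISO replicate 2). Neutrophil genes lay higher in ISO replicate 1 than in ISO replicate 2 by a median of 1.66. The mast cell list was not called (camera adjusted p = 0.546), with a median of 0.24 and 1 of 6 genes higher (1 when adjusted over the list alone), the stem cell factor receptor gene Kit, by 6.08-fold (10.2-fold without ISO replicate 2). Without ISO replicate 1, 2 mast cell genes rose and the median was 1.34, and without ISO replicate 2 it was -0.21. Red blood cell genes had a median of 2.02, with 3 of 7 higher (3 when adjusted over the list alone, camera adjusted p = 0.0134, adjusted p = 0.556 with an estimated correlation, and 0.113 by camera without ALLO replicate 2). Without ISO replicate 1, 7 of 8 tested were higher, and 1 was when either ALLO library was left out. The median was 3.06 without ISO replicate 1 and 1.39 without ISO replicate 2. Alas2, which encodes the haem synthesis enzyme of red cell precursors, rose 4.05-fold (7.61-fold without ISO replicate 1), a call lost without ALLO replicate 1 (edgeR adjusted p = 0.0862) and without ALLO replicate 2 (0.0749). Haemoglobin genes took 0.227% and 0.441% of ALLO counts and 0.164% and 0.0458% of ISO counts.

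All 15 genes of MHC class I presentation rose (15 when adjusted over the list alone), with a median of 2.07 (camera adjusted p = 6.34e-08, adjusted p = 0.555 with an estimated correlation). Nlrc5, the transactivator of class I genes, rose 10.0-fold, the immunoproteasome gene Psmb9 6.77-fold and H2-M3 4.19-fold. Class II presentation genes rose in 10 of 11 cases (11 when adjusted over the list alone), with a median of 5.02 (camera adjusted p = 3.55e-07, adjusted p = 0.555 with an estimated correlation). Ciita, the class II transactivator gene, was 32.5-fold higher (52.8-fold without ISO replicate 2) and the peptide-loading gene H2-DMa changed by 4.34 ± 0.40 (log2). The class II median was 5.62 without ISO replicate 1. The class I and class II genes belong to a family of related sequences, so that counts of single members are uncertain. The labels give no strain, and the build was mm10 for all libraries. Whether donor and recipient sequences of an allograft were counted alike was not tested. Strain and rejection therefore cannot be told apart in these counts.

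Interferon-gamma response genes rose in 16 of 21 cases (20 when adjusted over the list alone), with a median of 2.43 (camera adjusted p = 4.35e-08, adjusted p = 0.555 with an estimated correlation). Without ALLO replicate 1, 10 rose, and without ALLO replicate 2, 8, and the median was 3.19 without ISO replicate 2. Besides Cxcl9, the chemokine gene Cxcl10 rose 44.3-fold, the transcription factor gene Irf8 30.3-fold and the nucleic acid sensor gene Zbp1 19.1-fold. This list lay lower in ISO replicate 1 than in ISO replicate 2, in 18 of 21 members, by a median of -1.23. Type I interferon genes rose in 14 of 17 cases (17 when adjusted over the list alone), with a median of 2.11 (camera adjusted p = 1.98e-07, adjusted p = 0.555 with an estimated correlation). The antiviral gene Mx1 rose 14.6-fold and the RNA helicase gene Dhx58 8.62-fold.

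Chemokines and their receptors rose in 14 of 18 cases (14 when adjusted over the list alone), with a median of 3.61 (camera adjusted p = 3.03e-07, adjusted p = 0.555 with an estimated correlation). The median was 5.08 without ISO replicate 1 and 3.02 without ISO replicate 2. The chemokine receptor gene Cxcr4 was 36.9-fold higher and the ligand gene Cxcl16 17.3-fold. Leukocyte adhesion genes rose in 7 of 10 cases (8 when adjusted over the list alone), with a median of 3.87 (camera adjusted p = 6.31e-04, adjusted p = 0.555 with an estimated correlation). The leukocyte integrin gene Itgal rose 36.7-fold (56.9-fold without ISO replicate 1) and the endothelial ligand genes Icam1 and Vcam1 3.04- and 3.20-fold, while the selectin gene Selp had a change of -0.33 (edgeR adjusted p = 0.377). The adhesion median was 4.61 without ISO replicate 1. In the list of inflammatory cytokines and the inflammasome 9 of 14 rose (11 when adjusted over the list alone), with a median of 3.18 (camera adjusted p = 6.40e-06, adjusted p = 0.555 with an estimated correlation). The median was 3.94 without ISO replicate 1. Gsdmd, the pore-forming gasdermin, rose 6.86-fold, Casp1, its protease, 9.63-fold, and the cytokine gene Il6, at 0 counts in ISO, was at least 15.7-fold higher. Complement genes rose in 8 of 12 cases and fell in 1 (9 and 1 when adjusted over the list alone), with a median of 2.31 (camera adjusted p = 0.00119, adjusted p = 0.556 with an estimated correlation). Without ALLO replicate 1, 4 complement genes rose, none fell without ISO replicate 2 or ALLO replicate 2, and the median was 3.13 without ISO replicate 1 and 1.65 without ISO replicate 2. The anaphylatoxin receptor genes C5ar1 and C3ar1 rose 14.1- and 29.2-fold (C5ar1 by 4.52 on the log2 scale and C3ar1 83.6-fold without ISO replicate 1, C3ar1 17.3-fold without ISO replicate 2).

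Cell cycle genes rose in 19 of 20 cases (20 when adjusted over the list alone), with a median of 3.50 (camera adjusted p = 7.91e-09, adjusted p = 0.555 with an estimated correlation). The cyclin gene Ccnb1 was 18.6-fold higher and Rrm2, a subunit of ribonucleotide reductase, 12.0-fold. Immediate early genes had a median of -0.77, and 1 of 10 fell (1 when adjusted over the list alone, camera adjusted p = 0.0274, adjusted p = 0.566 with an estimated correlation), the transcription factor gene Fosb, by 4.95-fold. Without ISO replicate 1, 2 fell, and without ALLO replicate 2 4 fell and the median was -1.15. The list's call was lost without ISO replicate 2 (camera adjusted p = 0.0896) and without ALLO replicate 1 (0.106).

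Oxidative phosphorylation genes of the nuclear genome had a median of -0.34, and 2 of 16 fell (2 when adjusted over the list alone, camera adjusted p = 0.0190, adjusted p = 0.555 with an estimated correlation). Under scaling by library size alone the median was -0.15 and the call was lost (camera adjusted p = 0.0622). Without ALLO replicate 2, 5 fell. The complex I genes Ndufb8 and Ndufa4 fell 2.82- and 2.46-fold. Genes of the mitochondrial genome took 9.02% and 5.42% of ISO counts and 1.92% and 1.87% of ALLO counts. Fatty acid oxidation genes were not called (camera adjusted p = 0.0646, but 0.0352 without ISO replicate 2 and 0.0383 with fry), with a median of -0.33, 4 of 15 lower and 1 higher (the same when adjusted over the list alone). Only 2 were lower without ISO replicate 1, without ISO replicate 2 or without ALLO replicate 1, and none higher without either ISO library. Fabp3, the heart fatty acid binding protein gene, fell 18.8-fold and Acadm, a dehydrogenase gene, 2.12-fold.

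Adipocyte genes went both ways, with a median of 0.23, a mean of -0.82, a camera direction of up and a fry direction of down, and no call (camera adjusted p = 0.967). Of 13 members 4 fell and 2 rose (4 and 4 when adjusted over the list alone), and 1 rose without either ISO library. The lipid droplet gene Plin4 fell 7.32-fold, and Cidea, a gene of thermogenic fat, 20.0-fold (57.9-fold without ALLO replicate 1, 11.9-fold without ALLO replicate 2), while the droplet gene Cidec rose 3.30-fold. The skeletal muscle list was not called (camera adjusted p = 0.665), with a median of 0.65 and 1 of 6 lower (none when adjusted over the list alone). That gene was Ckm, the muscle creatine kinase, with 2 counts in ALLO and 70 in ISO, a ratio of 43.1 (95% counting interval 7.25 to 1752), a call lost without ALLO replicate 1 (edgeR adjusted p = 0.157) and without ALLO replicate 2 (0.0964), with limma-voom (0.0712), library size only (0.0516), a mean count of 10 or more (0.0580) and against 1.5-fold (0.0622). The median was -0.13 without ALLO replicate 1 and 0.04 without ALLO replicate 2. Without ISO replicate 2, Ckm fell below the filter on low counts and was not tested, so its call rests on that library. Schwann cell and nerve genes were not called (camera adjusted p = 0.0717, but 0.0448 without ISO replicate 1 and 0.0143 without ALLO replicate 1), with a median of 2.19, 5 of 10 higher and 1 lower (7 and 2 when adjusted over the list alone). Without ALLO replicate 1, 8 of 11 tested rose, 3 of 10 rose and 2 fell without ALLO replicate 2, and the median was 3.05 without ISO replicate 1 and 1.37 without ALLO replicate 2. The myelin gene Mbp rose 12.3-fold (18.9-fold without ISO replicate 1), and Ncam1, a neural adhesion gene, fell 9.44-fold. Another member, Prx, had a change of -1.18 (edgeR adjusted p = 0.0737). It passed as lower without the filter on low counts (edgeR adjusted p = 0.0445), with DESeq2 (0.0299) and with limma-voom (0.0446).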

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

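No gene called in ALLO against ISO changed sign in any alternative that tested it, with at least 5277 (halved counts) of the 5469 tested in each. Of the alternatives, halved counts (5628 genes called) and removal of X and Y genes (5280) were chosen after the data were seen. The count of called genes, 5469, ranged from 5037 (mean count of 10 or more) to 6592 (DESeq2 Wald test) across other scalings, filters and tests, apart from glmTreat, which tests against 1.5-fold and called 3805, with 1565 lower. Leaving out 1 library gave 3603 to 4651 called genes, 2054 to 2506 higher and 1512 to 2245 lower, the lowest total and the lowest number of lower genes being without ISO replicate 2. In these fits the lone library is assumed to vary like the other group. Of 34 lists, 26 were called, 0 with an estimated correlation (the median p over lists was 0.288), 14 with fry and 24 to 27 without 1 library. fry lost the calls of the elastic fibre (adjusted p = 0.80), immediate early (0.219), B cell (0.166), red blood cell (0.159), endothelial (0.122), neutrophil (0.118), matrix remodelling (0.118), lymphatic endothelial (0.113), complement (0.113), plasma cell (0.105), macrophage and monocyte (0.0588), dendritic cell (0.0578) and oxidative phosphorylation (0.0569) lists. The cause was not tested.

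The adipocyte list, not called, turned from up to down with fry (adjusted p = 0.712), library size only (0.938) and a mean count of 10 or more (0.887), and without ISO replicate 1, ISO replicate 2 and ALLO replicate 1 (range over the fits without 1 library 0.497 to 0.987). The skeletal muscle list did so without ISO replicate 1 (0.762, range 0.478 to 0.987). Log2 changes of uncalled genes also turned. Over the fits without 1 library Hdc ranged from -0.12 to 1.88, Mcpt4 from -1.41 to 1.02, Cpa3 from -1.99 to 0.56 and Ltbr from -0.51 to 0.11, and Ltbr was 0.0063 with library size only. The cause was not tested.

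With a replicate block 4873 genes were called, of which 4581 were also called without it, and 26 lists, and the adipocyte list, uncalled, turned to down (adjusted p = 0.772). The numbers do not pair the samples, since differences between replicates 1 and 2 in ISO and ALLO had a Pearson correlation of 0.0974 and a Spearman correlation of -0.02 across genes, which are not independent. Simulated 2-fold changes were recovered in 2% of cases, but 123 genes were called there against 5469 in the data. The adjusted threshold was thus stricter in the simulation, and 2% is not the power of this comparison. Genes not called may still differ.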

Other observations

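All tests in this part were chosen after the results were seen, including the thresholds by which each explanation was judged, which were set with the values already known. The genes named here were chosen after their values were seen.

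Among single genes that the lists did not cover, the mesodermal forkhead gene Foxf1 fell 14.8-fold and Gata6, a regulator of smooth muscle, 4.44-fold, while Meox1 rose 5.07-fold. Of 9 basement membrane and adhesion genes 5 fell, 1 rose and 3 did not pass, and 8 fell without ALLO replicate 2. Col4a6 fell 55.1-fold, Col4a5 19.8-fold and Npnt, a ligand of the Itga8 integrin, 29.2-fold, whereas Nid1 rose 2.02-fold, a call lost without ISO replicate 1 (edgeR adjusted p = 0.188), without ISO replicate 2 (0.152) and without ALLO replicate 1 (0.0532). The heat shock genes Hspa1a and Hspa1b fell 36.2- and 36.0-fold, values that are uncertain singly because the copies are nearly identical. Of 17 circadian clock genes 5 fell, led by Npas2 at 17.1-fold, and 2 rose, among them Per3 at 2.72-fold, while 3 fell and 1 rose without ALLO replicate 1, and 4 rose without ISO replicate 2.

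Immunoglobulin in ALLO grafts was mostly of the IgG classes. Ighg2c took 1.62% and 0.653% of the counts of ALLO replicates 1 and 2, Ighg2b 1.63% and 0.341%, and Igha 0.231% and 0.237%. V gene use was spread over many genes, with 99 and 92 heavy chain V genes detected, of which 11 and 7 made up 50% of V counts. The most counted were Ighv1-81 in replicate 1, at 7.10% (95% Wilson interval 6.98 to 7.23), and Ighv2-9-1 in replicate 2, at 15.5% (15.1 to 16.0), and 3 genes were shared among the 10 most counted. V genes are similar in sequence, so single shares are uncertain.

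Smooth muscle genes fell together in ALLO grafts. Dilution of all graft cells alike by infiltrating cells would, on its own, lower other resident types as much. The smooth muscle median lay -3.64 (log2) from that of fibroblasts (permutation p = 1e-05 across genes, the smallest that 100000 permutations can give). It lay -3.23 from that of the endothelium (permutation p = 2e-05). Genes were shuffled as if independent, but smooth muscle members moved together (estimated correlation 0.805), so these p-values do not measure the spread between libraries. The medians argue against dilution alone only if the fibroblast and endothelial lists track resident cells otherwise unchanged, which was not tested. Scaling is argued against because the median nearest 0 among 4 other fits was -3.65. Whether cells were lost or each cell made fewer transcripts cannot be told apart, since members fell unequally (SD 1.10 beside a median SE of 0.434) and other cells express some of them. A loss of smooth muscle cells or of their contractile programme may each contribute, as hypotheses.

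Of 27 Hox genes tested, 8 rose, including Hoxa10 at 10.0-fold and Hoxd9 at 12.0-fold, and 10 fell, including Hoxb2 at 13.1-fold, and across the alternatives 4 (without ALLO replicate 2) to 8 rose and 9 to 12 fell. That 8 rose argues against dilution alone only if the infiltrating cells carry none of these transcripts, which was not settled. Within the clusters the log2 change rose with the Hox number (Spearman rho = 0.58, two-sided permutation p = 0.00722, across genes, which are not independent), but cluster B did not follow (rho = 0.26), with none of 8 higher and 6 lower, Hoxb8 by 8.79-fold and Hoxb6 by 6.04-fold, and no gene of cluster C fell. Cells of a more posterior body level in ALLO grafts are a candidate source for part of this at most, and that correlation restates the pattern from which the hypothesis came. Leukocytes as the source of Hoxa11, Hoxc9, Hoxc10 and Hoxd10 stay open, because these had 2 counts in ISO replicate 1 where its Ptprc count gives 17.8, but 8 in ISO replicate 2 where 4.16 are given, both near the floor.

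ISO replicate 1 stood apart from ISO replicate 2, with 10647 against 8 Xist counts, 0 against 2312 Ddx3y counts and 279 against 8916 Apoe counts, while both ALLO libraries had Ddx3y (2287 and 2105) and few Xist counts (6 and 0). Carry-over from an ALLO library is argued against as the whole cause, because Igha made up 53.3% (95% Wilson interval 51.7 to 55.0) of Igha plus Igkc counts there and 8.30% and 21.2% in the ALLO libraries, and 8 counts of 4 Y genes were found where 47.7 would come along. An ALLO graft under a wrong label is argued against by the smooth muscle list, which differed by -0.0331 (log2) from ISO replicate 2. Fewer macrophages would not give the low Apoe count, since the macrophage list was higher by 1.58. The Xist and Y counts mark tissue of different sex in the ISO libraries, but how far sex underlies the other differences, such as Apoe, and whether strain or genotype may, stays open, untested, as the labels give none of these.

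Saa3 had 6025 counts in ISO replicate 1 and 48 in ISO replicate 2. The clock gene Dbp had 30 and 317 counts in ISO replicates 1 and 2, and Nr1d1 659 and 4250. The noradrenaline synthesis genes Th and Dbh had 0 counts in ISO, 4 and 20 in ALLO replicate 1, and 287 and 794 in ALLO replicate 2. Dbh was not called (edgeR adjusted p = 0.0633), and most of its counts came from ALLO replicate 2.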
